A study of Mus musculus with 54 samples.

How the data were processed

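Fetal liver progenitors of Wt, Ebf1-KO and E2A-KO mice, cultured on OP9 cells with KIT ligand, FLT3 ligand and interleukin-7, and an Abelson-transformed progenitor B cell line were profiled by ATAC-seq, ChIP-seq, CUT&RUN and PLAC-seq, per the labels' protocols. Ebf1-KO cells with an Ebf1ER vector were sampled at 0, 6, 24 and 72 h of 4OHT. The 54 samples fell into 40 groups by assay, target, genotype and time, and nothing in the labels says that replicates came from separate animals.

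The submitters' processing notes name Bowtie2 2.3.5, SAMtools 1.9, deepTools 3.3.1, HOMER 4.10, Trim Galore 0.6.4 and HiC-Pro 2.11.1, and Picard, MACS2, FastQC and edgeR without versions, with the genome build mm10 (GRCm38.p5). The signal values of the region tables are tags per region that the authors scaled to 10000000 tags per library with HOMER, per the file headers, and they were not divided by region length. The header gives each library's total, and value times total over 10000000 returned whole tags, or multiples of 0.5 tag for H3K27me3 and CUT&RUN H3K27ac, within 0.1 tag in every region. The PLAC-seq list holds the contact count of each pair of 5 kb bins and a bias-corrected q-value, as deposited, at a q threshold of 0.05 per the labels' file names. The Fli1 and Ikzf1 lists carry a peak score as the authors' peak caller gave it against input, per the file headers, and they come from the Wt libraries. The accessible regions of the Abelson line were deposited as a list of annotated peaks whose score column is 0 throughout, so those scores were not used. Ebf1-bound regions and Pax5 peaks rest on the peak lists named in the deposited tables. These lists come from the Abelson line, so binding in the fetal liver progenitors or in the Ebf1ER cells was not measured.

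Each group of a region table was 1 column. Columns were pools of libraries for ATAC, H3K4me3 and H3K27me3 and single libraries otherwise. The tests planned across replicates (limma on log values) could therefore not be made, and values, ratios and medians are given instead, as the plan foresaw for pooled columns. The Wt ATAC column is named as a pool of 6 libraries with a fragment size setting of 180, where 3 Wt samples are labelled, and its name does not mention the removal of mitochondrial reads. The 6 h and 72 h totals, 34710011 and 34710016 tags, are nearly the same, though the values of these columns differ. The 2 columns of Ebf1-KO and Pax5-KO ATAC values in the accessibility table were not used, since no sample is labelled for them. Input and IgG libraries, Fli1 and Ikzf1 in Ebf1-KO, and gene expression were not analysed here.

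For each comparison the log2 ratio of value plus 1 was computed per region. Regions with a ratio of at least 2 on that scale were counted in either direction. Values carry exact Poisson 95% intervals from the recovered tags, and fold ratios of tags carry exact conditional intervals. Medians over regions carry exact order-statistic intervals, differences of medians bootstrap intervals from 2000 draws, and shares carry Wilson intervals. These intervals hold counting error or the spread over regions, not differences between animals or cultures. TMM factors came from calcNormFactors of edgeR 4.0.16 on the recovered tags of each table. Where the median of all regions lay more than 0.1 from 0, ratios are also given relative to it. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

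Region classes (open in both genotypes or in Wt only, promoter or not, Ebf1-bound and open or closed in Ebf1-KO) are those of the deposited tables, matched to the E2A table by position. The gene of a region is the nearest transcription start in the authors' annotation, so an intron or exon may belong to a neighbouring gene. Regions lay near genes the authors had selected as enriched in Wt. The 12 gene lists, among them natural killer, erythroid, housekeeping and stromal genes as outside lists, the named-gene rule, the classes and most alternatives were fixed before the data were examined. TMM for the class medians of marks and factors, the summed values and the window of region lengths from 500 to 1000 bp were added later. Per comparison, the rule names the 8 regions with the largest log2 ratios in each direction among those whose larger value is at least 20 tags, with at most 1 region per gene. It adds up to 4 genes per list by highest mean value, each by its strongest region. Regions of Ebf1, Pax5, Tcf3, Cd79a, Igll1, Vpreb1, Rag1 and Foxo1 may be named wherever they occur, and 1 further gene of this rule is not reported here. For PLAC-seq it names the 10 listed promoters with most interactions. Fcrl1 and Btk, the exceptions among receptor genes in E2A-KO, and the summed Y-linked values were chosen after their values were seen, as were the listed genes named by their Fli1 and Ikzf1 peaks. A list of at least 3 measured genes is given with the percentile of its median among 10000 random lists of the same size matched on mean signal in 10 bins.

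Peaks were assigned to Ebf1-bound regions by an overlap of at least 1 bp and compared between open and closed regions by Fisher's exact test over regions, adjusted over 2 tests by Benjamini-Hochberg. The same overlap placed accessible regions in PLAC-seq anchors. The alternatives tried were TMM scaling, a pseudocount of 5, only regions with a mean of at least 10 tags, other overlap rules, and the stricter q and contact limits.

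The count of 2-fold differences was tested on simulated data with the real means and totals, in 20 simulations with 200 regions set to a known ratio. Tags were drawn with Poisson counting error only, without spread between libraries or cultures and without a difference in scaling. The shares below are therefore not error rates for differences between conditions. Unchanged regions passed the ratio of 2 in 0.0220% of cases for E2A-KO, 0.864%, 0.628% and 0.592% for 6, 24 and 72 h, 0.0126% for H3K4me3, 0.00701% for H3K27me3, 0.557% for H3K4me2, 0.237% for H3K27ac, 1.95% for PolII, 0.0669% for BRG1, 0.231% for EP300 and 0.813% for PolII at Ebf1-bound regions. Regions set to 4-fold were recovered in 95.3%, 94.6%, 95.5%, 95.2%, 92.7%, 39.9%, 95.7%, 95.8%, 94.0%, 98.3%, 97.5% and 96.8% of cases in that order. Regions set to 2-fold, at the limit itself, were recovered in 27.1% for E2A-KO, 37.5% for 72 h, 25.6% for H3K4me3, 6.14% for H3K27me3 and 41.0% for PolII. Regions set to 8-fold were recovered in at least 96.8% except for H3K27me3, at 54.7%, whose low tag numbers hide many differences.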

Results

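Chromatin of cultured mouse fetal liver B-cell progenitors was measured in cells that carried or lacked the transcription factors E2A (encoded by Tcf3) or Ebf1. The 54 labelled samples came from progenitors labelled pro-B of wild-type (Wt), Ebf1-KO and E2A-KO fetuses expanded on OP9 stroma, and from an Abelson-transformed progenitor B cell line (the Abelson line below). Accessibility (ATAC-seq) was labelled for 3 Wt and 3 E2A-KO samples, for 2 samples of the Abelson line, and for 2 samples at each of 0, 6, 24 and 72 h of 4OHT in Ebf1-KO cells transduced with an inducible Ebf1ER protein. ChIP-seq of H3K4me3 and H3K27me3 had 2 samples per genotype (Wt and Ebf1-KO). H3K4me2, RNA polymerase II (PolII), BRG1, EP300, Fli1 and Ikzf1 had 1 per genotype, as had CUT&RUN of H3K27ac. Promoter-anchored contacts in the Abelson line came from 2 H3K4me3 PLAC-seq samples.

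Every group of the region tables was a single column, either pooled or from a single library, so there were no replicates to test across, and all differences below compare these libraries rather than the conditions in general. Values are tags per 10000000 sequenced tags of a library, called tags below, at regions of the mm10 build, with 95% intervals for counting error only. Library totals were 153781074 tags for Wt ATAC and 85771440 for E2A-KO, then 47293654, 34710011, 36612801 and 34710016 for 0, 6, 24 and 72 h of 4OHT. For Wt and Ebf1-KO they were 76632191 and 196071042 for H3K4me3, 69807044 and 77280688 for H3K27me3, 41164505 and 41703732 for H3K4me2, and 24557525 and 27016459 for H3K27ac. They were 25628369 and 29238586 for PolII, 52852376 and 47681817 for BRG1, and 41086404 and 63819568 for EP300. The regions lay near genes that the study had selected as enriched in Wt, so a lower signal in a knockout at such genes is not independent evidence about them. "Open in both" means accessible in Wt and in Ebf1-KO cells, "open in Wt only" means accessible in Wt and not in Ebf1-KO cells. "Ebf1-bound" means bound by Ebf1 in the Abelson line, not in the progenitors or the Ebf1ER cells.

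The comparison of E2A-KO with Wt asked which accessible regions near B-lineage genes need E2A, a factor that acts before and together with Ebf1. Accessibility was far lower in E2A-KO cells at the genes that build the pre-B-cell receptor, such as Igll1, Cd79a and Vpreb1. Pou2af1, Lef1, Rag2 and the Pax5 promoter also had much lower signal. By contrast, the promoters of Ebf1 and Tcf3 and the first exon of Foxo1 differed about as much as the typical region or less. Regions open in Wt only had the lowest ratios.

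At the genes of the surrogate light chain and of the receptor's signalling chain, the Igll1 promoter (chr16:16863729-16864437) held 7.11 (5.44–9.13) versus 97.4 (92.5–102) tags (E2A-KO first, Wt second), 13.7-fold (10.6–17.997) lower. The Cd79a promoter (chr7:24896982-24897767) held 8.04 (6.26–10.2) versus 74.6 (70.3–79.0), 9.27-fold (7.27–12.0) lower. At the Vpreb1 promoter (chr16:16869013-16869518) the values were 5.01 versus 32.1, a log2 ratio of -2.46. Signalling adaptors were lower too, with 22.7 versus 114 at the Pik3ap1 promoter (chr19:41384436-41385644) and 42.8 versus 109 at the Dok3 promoter (chr13:55527206-55529745). Of the 16 measured genes of pre-B-cell receptor signalling, 14 were at least 2-fold lower in their strongest region and 11 under TMM, with a median log2 ratio of -2.34. The 2 that were not were Fcrl1 and Btk, at -0.74 and -0.53, and relative to the median of all regions they stood at 0.02 and 0.23.

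Among B-lineage transcription factors, the promoter of the coactivator Pou2af1 (chr9:51212995-51214114) was 12.2-fold (9.85–15.4) lower, at 10.0 versus 123. An intergenic region upstream of Lef1 (chr3:131106026-131107747), a regulator of pro-B cell survival, was 6.55-fold (5.56–7.77) lower. The Pax5 promoter (chr4:44710621-44711145) held 2.91 (1.88–4.30) versus 18.1 (16.0–20.3), at a log2 ratio of -2.29. Foxo1, which drives Rag expression, had a distal region (chr3:52443632-52444742) at 15.4 versus 104 and a first exon (chr3:52267610-52270385) at 65.9 versus 101.4. The exon's log2 ratio of -0.61 was 0.15 relative to all regions and 0.28 under TMM scaling, so its direction flipped. The Ebf1 promoter (chr11:44616860-44617600) was at 33.0 (29.3–37.1) versus 58.3 (54.5–62.2), a log2 ratio of -0.80 that flipped to 0.08 under TMM. The Tcf3 promoter (chr10:80433920-80434318) was at 40.7 versus 52.4, and its -0.36 flipped to 0.53, while an intronic Tcf3 region (chr10:80429707-80430593) was lower at 11.4 versus 47.7. These Tcf3 regions say nothing about the deletion itself, whose position the labels do not give. The Tcf4 promoter, of another E-protein gene, held 37.5 versus 76.1.

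The recombination gene Rag2 had 6.76 (5.13–8.74) versus 58.0 (54.3–61.9) at chr2:101598305-101599187, 8.58-fold (6.57–11.4) lower, and the Rag1 promoter (chr2:101649360-101649875) had 11.1 versus 32.4. Dntt, which adds nucleotides at V(D)J joints, was at 4.08 versus 15.2, and the DNA ligase gene Lig4 at 54.0 versus 90.7, level with the median of all regions (relative log2 0.02, and 0.15 under TMM, where its direction flipped). Among surface proteins, an intronic region of Bst1 (chr5:43824304-43825074), which encodes the early lymphocyte antigen BP-3, was 10.8-fold (9.08–12.9) lower. The chemokine receptor gene Cxcr4 (77.8 versus 190.3), Cd24a (55.0 versus 122) and Cd55 (18.4 versus 53.9) were lower by smaller ratios. Id3, an inhibitor of E proteins, and Fli1 were the measured progenitor factors, at 32.3 versus 76.2 and 20.8 versus 87.6. The cell cycle and survival regulators stood out in the other direction, since Bcl2l1 (84.4 versus 144), Cdkn2c (53.0 versus 66.3), Ccnd3 (38.8 versus 65.3) and E2f2 (19.1 versus 18.7) were all at or above the median of all regions. Their median log2 ratio of -0.32 was 0.44 relative to all regions, and all 5 measured genes lay above 0 under TMM.

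The largest ratios were at the promoter of the interleukin-5 receptor gene Il5ra (chr6:106748844-106749506), 2.56 (1.60–3.88) versus 144 (138–149.7) and 56.0-fold (36.9–89.5) lower, and at an intron of Alpl (chr4:137788264-137789248), 32.1-fold (24.0–43.9) lower at 5.36 versus 172. Regions near Ufm1 (3.73 versus 86.2), Col6a6 (3.15 versus 74.4), Tbc1d32 (2.91 versus 71.1) and Ank2 (0.58 versus 33.0) followed. With library totals few regions were at least 2-fold higher in E2A-KO, while 294 were so under TMM. An intronic region of Scaf11 (chr15:96377236-96377652) was 8.24-fold (5.88–11.8) higher at 22.5 versus 2.73, an intron of Foxred2 (chr15:77945496-77946348) was 4.89-fold (3.81–6.32) higher at 27.98 versus 5.72, and regions near Slc5a10 (20.99 versus 5.01), Tbc1d4 (20.99 versus 6.37) and Tbc1d9 (31.0 versus 11.8) were higher too.

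Across all 4983 regions near 1788 genes, the median log2 ratio was -0.76, with medians of 5.83 and 11.9 tags. At least 2-fold lower were 1889 regions and at least 2-fold higher were 49, against 750 and 294 under TMM, where the median was 0.02. Below 0 were 87.4% of regions, and 48.8% under TMM. The 785 non-promoter regions open in Wt only had a median of -1.58 (-1.65 to -1.52), 572 (72.9%) of them at least 2-fold lower and 0 higher, and relative to all regions they stayed at -0.82. Their 70 promoters were at -1.30, with 45 (64.3%) lower. Regions open in both genotypes were at -0.82 away from promoters (2397 regions, 41.5% at least 2-fold lower) and -0.84 at 512 promoters (36.5%), and the 1219 regions in neither class were at -0.25. Under TMM, the medians of these last 3 groups flipped to 0.01, 0.02 and 0.35.

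**Figure D1:**
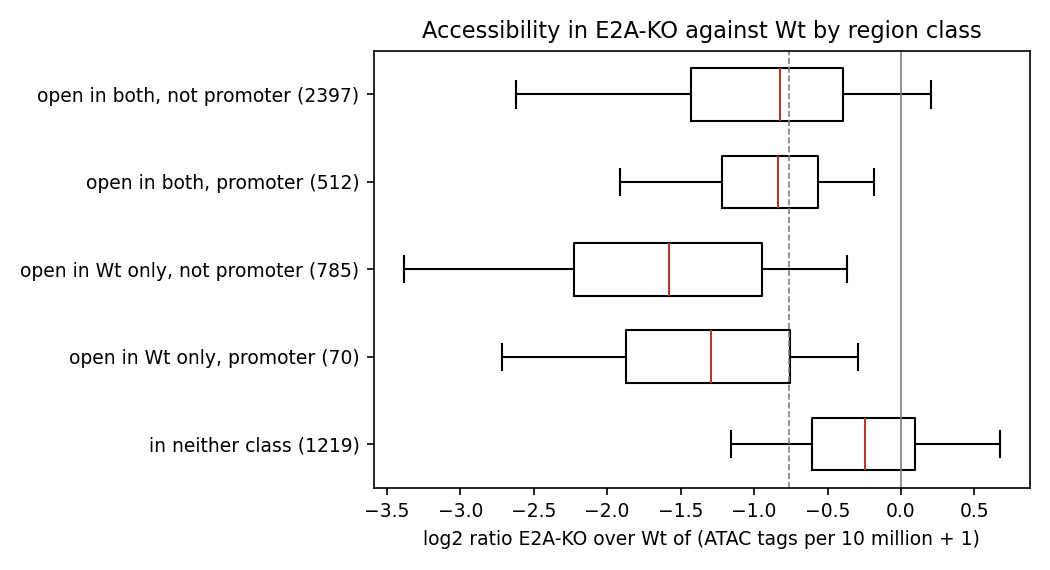
Accessibility of E2A-KO over Wt by region class: log2 ratio of ATAC tags per 10000000 plus 1 (x axis) for each class (y axis), with boxes for quartiles, whiskers for the 5th to 95th percentile and red lines for medians. Regions open in Wt only had medians of -1.58 (785 non-promoter regions) and -1.30 (70 promoters); the dashed line is the median of all regions, -0.76, which was 0.02 under TMM scaling.

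By gene list, the median of pre-B-cell receptor signalling genes was lower than in all but 0.02% of random lists matched on signal. Cytokine receptors and surface proteins (7 genes, median -1.50) stood at percentile 3.91, recombination genes (4 genes, -1.57) at 11.9, and B-lineage factors (13 genes, -1.0) at 45.6. Cell cycle regulators (5 genes, -0.32) stood at 98.0, and 3 myeloid genes, Csf2ra, Lyz2 and Csf2rb (-0.47, above 0 under TMM), at 63.0. The T-lineage list had Cd5 alone, at 6.30 versus 10.9, where -0.70 flipped to 0.11 under TMM, and the natural killer, erythroid, housekeeping and stromal lists had 0 measured genes in the region tables. These percentiles describe the libraries at hand.

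The 4OHT time course asked how accessibility at Ebf1-bound regions differs once Ebf1ER is activated in Ebf1-KO cells. No sample is labelled as treated with 4OHT without Ebf1ER. Effects of 4OHT itself and of time in culture therefore cannot be told apart from those of Ebf1ER. The promoters of Igll1 and Cd79a carried steadily more signal from 0 to 72 h, and 1 of the 2 distal Foxo1 regions followed the same order. Vpreb1, by contrast, stayed near the detection limit at every time. Survival and cell cycle genes with strong signal, such as Bcl2l1 and Cdkn2c, differed less.

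At 0, 6, 24 and 72 h, the Igll1 promoter held 4.65, 12.4, 19.1 and 36.6 tags, 7.87-fold (4.98–13.0) higher at 72 h than at 0 h. The Cd79a promoter held 5.07, 13.8, 20.2 and 31.4, 6.19-fold (3.95–10.1) higher at 72 h. The distal Foxo1 region (chr3:52443632-52444742) held 13.7, 17.9, 24.9 and 44.7, 3.25-fold (2.42–4.41) higher at 72 h, while the other distal Foxo1 region (chr3:52457979-52459184) held 7.82, 12.4, 8.47 and 11.5, a difference not detectable at this depth. Counting intervals of the first and last time did not overlap for Igll1, 36.6 (30.5–43.5) versus 4.65 (2.91–7.04) at 72 h versus 0 h, nor for Cd79a, 31.4 (25.8–37.9) versus 5.07 (3.25–7.55). At the Vpreb1 promoter (chr16:16869013-16869570), closed in Ebf1-KO, 1.73 (0.635–3.76) versus 2.54 (1.31–4.44) left a difference not detectable at this depth. An intergenic region nearest Vpreb2 (chr16:17968914-17970011), not its promoter, held 44.7 versus 17.97 at 72 h versus 0 h. The adaptor genes Pik3ap1 (60.8 versus 25.2) and Dok3 (51.3 versus 28.1) and the kinase gene Blk (60.8 versus 35.1) were higher at 72 h as well.

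Lineage factors gave a mixed picture at 72 h. Tcf3 had 21.03 versus 12.3 at chr10:80442655-80443733 and 10.7 versus 6.77 in its intron (chr10:80429685-80430593). The Ebf1 region at chr11:44612343-44613605 had 10.4 versus 9.52, Spib had 60.8 versus 54.1, Tcf4 39.8 versus 33.8 and Lef1 20.5 versus 15.9, all 4 below 0 under TMM though above 0 with library totals. Bst1 (99.4 versus 54.1) and Cd24a (84.1 versus 42.7) were higher at 72 h, Cd38 (9.22 versus 4.44) by fewer tags, and Cxcr4 (35.4 versus 31.7) was below 0 under TMM only. Rag2, at a region closed in Ebf1-KO, had 13.8 (10.2–18.3) versus 5.92 (3.93–8.56), and Dntt had 4.61 versus 4.23, below 0 under TMM only. Bcl2l1 (125 versus 88.8), Cdkn2c (76.1 versus 67.9) and Ccnd3 (45.5 versus 39.3) were above 0 in log2 ratio with library totals and below 0 under TMM. Fli1 (33.1 versus 19.4), Cd5 (9.80 versus 4.86) and Id3 (24.8 versus 17.1, below 0 under TMM only) completed the listed genes.

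The largest 72 h ratios were at an intronic region nearest Derl1 (chr15:57809530-57810232), 38.0 (31.8–45.1) versus 3.17 (1.77–5.23) and 12.0-fold (7.01–22.03) higher, the Apbb1 promoter (chr7:105568490-105569791), 7.37-fold (5.22–10.7) higher, and 2410012E07Rik (chr14:70849759-70850747) at 53.9 versus 7.40. Among regions closed in Ebf1-KO, Klf10 (chr15:38280174-38280854) was 7.69-fold (4.32–14.7) higher. At 6 h the largest ratios were at 2410012E07Rik, already 4.24-fold (2.88–6.40) higher, the Fam129c promoter (chr8:71597229-71598211; 24.5 versus 6.13), Prkce (40.9 versus 12.1) and Il16 (56.2 versus 19.2). At 24 h they were again 2410012E07Rik, 8.12-fold (5.66–12.0) higher, with Heyl (28.1 versus 4.44), Fam129c (33.9 versus 6.13) and Asb2 (42.6 versus 8.25). Lower values were small in size, such as Itpr3 at 6 h (19.6 versus 30.0), Bad at 24 h (25.7 versus 33.6) and Ccdc9 at 72 h (49.5 versus 60.9).

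Medians over the 256 regions closed in Ebf1-KO were 2.96, 3.75, 4.37 and 4.61 tags at the 4 times, and over the 916 open regions 13.6, 17.6, 21.6 and 22.2. The step from 24 to 72 h was small in both classes, at a median log2 ratio of 0.06 in closed and 0.05 in open regions, against 0.23 and 0.26 from 0 to 6 h. At least 2-fold higher at 72 h were 61 closed regions (23.8%, 19.0–29.4) and 152 open regions (16.6%, 14.3–19.1), against 1.05% and 0.0710% in simulated unchanged regions. At 24 h the shares were 22.3% and 14.4%, and at 6 h 8.59% and 5.24%. The mean log2 level of closed minus open regions was -2.06 at 0 h and -2.14 at 72 h, a difference of -0.07 (-0.18 to 0.02). From the summed values of each class that difference was 0.23, so these libraries did not settle which class differed more.

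The median of all regions was 0.26 at 6 h, 0.47 at 24 h and 0.50 at 72 h against 0 h, and -0.01, -0.05 and -0.06 under TMM. With library totals, 70, 189 and 213 regions were at least 2-fold higher and 7, 10 and 7 lower at the 3 times, and under TMM 40, 70 and 80 higher and 20, 31 and 32 lower. The shares above 0 were 77.0%, 85.8% and 86.8%, and 49.4%, 45.2% and 45.6% under TMM. Pre-B-cell receptor signalling genes (13 genes) had medians of 0.52, 0.79 and 1.24, at percentiles 98.7, 98.6 and 99.97 of matched lists, and 0.74 relative to all regions at 72 h. B-lineage factors (9 genes) were at 0.35, 0.68 and 0.35, at percentiles 69.6, 87.99 and 12.5. Cytokine receptors (5 genes) were at 0.49, 0.72 and 0.86, at 95.9, 92.5 and 96.6, and cell cycle regulators (3 genes) at -0.01, 0.25 and 0.21, at 3.15, 6.64 and 3.43.

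**Figure D2:**
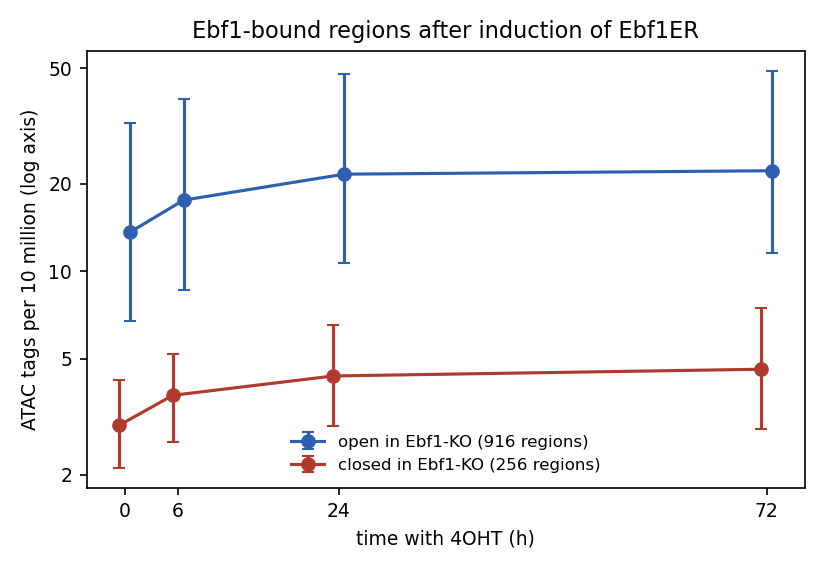
ATAC tags per 10000000 (log y axis) at Ebf1-bound regions against hours of 4OHT (x axis) in Ebf1-KO cells with Ebf1ER; dots are medians and bars quartiles of the 916 regions open (blue) and the 256 regions closed (red) in Ebf1-KO. Closed regions had medians of 2.96 tags at 0 h and 4.61 at 72 h, open regions 13.6 and 22.2; under TMM the 72 h median of open regions was -0.06 in log2.

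**Figure D3:**
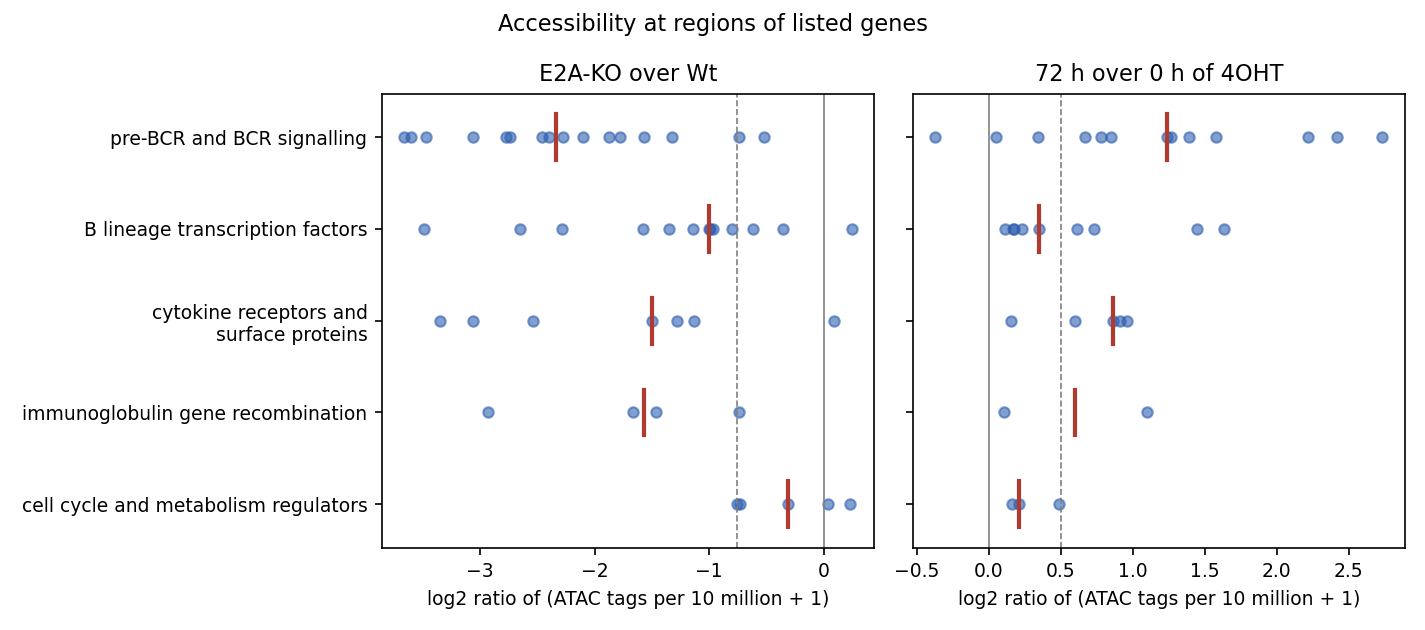
Log2 ratio of ATAC tags per 10000000 plus 1 (x axis) at the strongest region of each listed gene, by gene list (y axis), for E2A-KO over Wt and for 72 h over 0 h of 4OHT; dots are genes, red bars list medians and the dashed lines the medians of all regions. Pre-B-cell receptor signalling genes had medians of -2.34 and 1.24, against -0.76 and 0.50 for all regions (0.02 and -0.06 under TMM).

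The comparison of histone marks between Wt and Ebf1-KO asked which marks at B-lineage genes depend on Ebf1. H3K4me3 was many times higher in Wt at Pax5, Cd79a, Vpreb1, Igll1 and Pou2af1. The polycomb mark H3K27me3 covered Lef1, Ikzf3, Foxo1 and the Pax5 promoter in Ebf1-KO cells and was almost absent there in Wt. The Ebf1 promoter itself and cell cycle genes such as Cdkn2c and Bcl2l1 had more H3K4me3 without Ebf1, a direction shared by most promoters open in both genotypes. Ebf1 is the gene knocked out in these cells. Signal at the regions of Ebf1 itself in Ebf1-KO cells, here and below, is therefore no evidence of how Ebf1 acts on them.

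For H3K4me3, the Pax5 intronic region chr4:44709071-44709390 held 58.9 (53.5–64.5) versus 1.22 (0.781–1.82) tags (Wt first, Ebf1-KO second), 48.1-fold (31.9–75.8) higher in Wt. The Cd79a promoter was 31.2-fold (23.9–41.4) higher, at 94.0 versus 3.01, the Vpreb1 promoter 25.0-fold (18.04–35.6) higher, at 51.0 versus 2.04, and the Igll1 promoter 14.2-fold (11.3–18.01) higher, at 63.7 versus 4.49. Cd79b, the partner chain of Cd79a, had 91.9 versus 10.5 in an intron (chr11:106313636-106313923). Bst1 (chr5:43818730-43819486) had 122 versus 13.3 and Cd55 157 versus 19.5, whereas Cxcr4 was lower in Wt (331 versus 586) and Cd24a higher (410.0 versus 195). Rag2 had 18.01 versus 2.86 and Rag1 51.3 versus 39.6. Among factors, the exon of Foxo1 had 514 versus 366, Tcf4 142 versus 272, Irf8 167 versus 190.1 and Bcl11a 102 versus 158. At the Ebf1 promoter 59.9 (54.5–65.6) versus 126 (121–131) meant 2.106-fold (1.91–2.33) more in Ebf1-KO. The Tcf3 promoter was also lower in Wt (30.8 versus 78.4), and the Tcf3 intron higher (29.5 versus 2.35). Cdkn2c (157 versus 252), Ccnd3 (151 versus 247) and Bcl2l1 (73.3 versus 159) were lower in Wt, and the E-protein inhibitor gene Id3 higher (187 versus 75.9).

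Largest among H3K4me3 ratios higher in Wt were an intron nearest 4930480K15Rik (chr17:90454142-90455436), 286 versus 1.38 and 208-fold (142–316) higher, Chst3 (96.0 versus 1.79), Cplx2 (221 versus 5.05) and Pou2af1 (chr9:51212995-51214114), 42.6-fold (33.5–54.9) higher at 154 versus 3.62. The rest were Y-linked, with Kdm5d, Eif2s3y and Uty at 41.6, 38.1 and 36.4 in Wt and listed at 0 in Ebf1-KO, and Ddx3y at 45.7 versus 0.10. Summed over these 4 genes, H3K4me2 was 39.3 versus 0 and PolII 60.1 versus 0, while CUT&RUN H3K27ac was 84.5 (73.4–96.8) versus 102.9 (91.1–116). They are 4 of 3764 regions. Higher in Ebf1-KO were Xylt1 (chr7:117380855-117381785), 2.35 (1.39–3.71) versus 175 (169–181) and 74.3-fold (47.0–126) more, Casc1 (3.00 versus 70.8), Hsh2d (4.57 versus 119.5) and Plxdc1 (4.83 versus 152).

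H3K27me3 was low at most regions, with medians of 0.86 in Wt and 0.71 in Ebf1-KO, but reached high values at a few genes, mostly in Ebf1-KO. Lef1 (chr3:131106026-131107747) had 2.01 (1.10–3.37) versus 90.1 (83.5–97.0), 44.9-fold (26.6–82.6) more in Ebf1-KO, and the promoter of Ikzf3, a lymphoid zinc finger gene, 1.22 (0.543–2.36) versus 45.2 (40.6–50.2), 37.1-fold (19.0–84.2) more. The Foxo1 exon had 1.58 versus 36.7 and the Pax5 promoter 0.50 versus 22.6, 45.0-fold (16.3–189) more. Kirrel (chr3:87173827-87175113; 0.72 versus 67.5), Crhbp (1.00 versus 54.6), Myh10 (0.64 versus 43.4) and Klhl14 (1.07 versus 43.6) showed the same direction, as did Cd24a (1.36 versus 31.2), Cd55 (1.43 versus 23.2), Id3 (1.36 versus 15.8), Cd38 (1.65 versus 7.96), Cdkn2c (1.00 versus 7.70) and Blnk (2.22 versus 9.70). At Cd79a (0.43 versus 0.84), Igll1 (0.43 versus 0.52) and Vpreb1 (0.64 versus 0.06) no difference was detectable at this depth, so the low H3K4me3 of these genes in Ebf1-KO came without more than 1 tag of H3K27me3 in its place. Asap1 (39.7 versus 31.8) was the only region of at least 20 tags with more in Wt.

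H3K4me2 and H3K27ac mark primed and active elements, and Cd79a and an intron of Tcf3 had more of both in Wt. H3K4me2 was 35.7 versus 1.92 at Cd79a and 62.9 versus 5.04 at the Tcf3 intron, with Cd22 (chr7:30878512-30880167) 6.05-fold (4.70–7.89) higher and Lef1 at 179.5 versus 48.4. The Foxo1 exon had 4.23-fold (3.73–4.803) more H3K4me2 in Ebf1-KO, at 74.1 versus 313. More in Ebf1-KO was also found at Id3 (40.8 versus 115), Cxcr4 (29.4 versus 85.4), Cd24a (74.3 versus 168) and Pik3ap1 (48.6 versus 123). The largest ratios were at Crhbp (109 versus 1.44) and Cr2 (79.2 versus 2.40) in Wt and at Foxred2 (0.97 versus 47.2) and Plxdc1 (6.07 versus 86.1) in Ebf1-KO. H3K27ac at Cd79a was 50.7 versus 7.03, 7.21-fold (4.43–12.4) higher in Wt, with 58.2 versus 14.1 at Igll1, 28.7 versus 6.11 at Vpreb1 and 89.0 versus 21.8 at the adaptor gene Blnk. Pou2af1 had 67.4 versus 8.51, the distal Foxo1 region 83.1 versus 35.5, the Tcf3 intron 45.4 versus 4.81, Rag2 57.6 versus 10.4 and Ccnd3 72.9 versus 13.3. The Ebf1 promoter had 26.9 versus 22.6, a log2 ratio of 0.24 that flipped to -0.50 under TMM, and Cxcr4 had 93.9 versus 64.0, flipping from 0.54 to -0.22. The largest H3K27ac ratios were at Alpl (103 versus 3.33) and Ufm1 (66.6 versus 1.85) in Wt and again at Foxred2 (3.66 versus 25.0) in Ebf1-KO.

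The PolII comparison asked whether transcription machinery was present at the same regions. Igll1 held 141 (127–157) versus 3.76 (1.88–6.73), 37.5-fold (20.7–75.9) higher in Wt, Cd79a 63.2 versus 3.76 and Vpreb1 53.9 versus 3.08. Regions of factor genes were as strong, with Lef1 (chr3:131054138-131055139) 48.2-fold (24.2–113) higher at 132 versus 2.74, the distal Foxo1 region 22.6-fold (13.7–40.03) higher at 124 versus 5.47, and the Pou2af1 promoter at 93.3 versus 3.76. All 4 measured recombination genes had at least 2-fold more PolII in Wt at their strongest regions, which need not be promoters, and 3 of them under TMM. The values were 56.2 versus 9.23 for Rag2, 26.5 versus 6.16 for Rag1, 42.1 versus 2.74 for Dntt and 40.2 versus 12.3 for Lig4. Bst1 (111 versus 25.0), Cd24a (81.9 versus 10.3) and Fli1 (95.6 versus 17.4) were higher in Wt. The Ikzf3 promoter held 35.1 (28.2–43.2) in Wt and was listed at 0 in Ebf1-KO. The promoters of Ebf1 (9.75 versus 19.8) and Tcf3 (10.9 versus 23.9) had less PolII in Wt, and Spib (49.5 versus 48.6) was level, its log2 ratio of 0.03 flipping to -0.69 under TMM. Cdkn2c (28.9 versus 30.1) and Bcl2l1 (41.0 versus 36.9, flipping from 0.15 to -0.57) were near level as well, and the immediate-early gene Fosb was 11.2-fold (6.72–19.9) lower in Wt (6.24 versus 69.8).

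Over the 3764 regions, those open in Wt only had higher Wt over Ebf1-KO ratios of every active mark than those open in both, as the plot of class medians shows. The median log2 ratio for H3K4me3 was 1.18 in 855 regions open in Wt only and -0.28 in 2909 open in both, for H3K4me2 1.63 and -0.09, for H3K27ac 1.57 and 0.52, and for PolII 1.57 and 0.48. Among regions open in both, the 512 promoters were at -0.49 for H3K4me3, with 72.1% below 0. H3K27me3 went the other way, at -0.15 and 0.10, a difference of -0.25 that shrank to -0.0696 with a pseudocount of 5. With a mean of at least 10 tags, H3K27me3 at regions open in both away from promoters turned to -1.63. At least 2-fold higher in Wt among regions open in Wt only were 53.8% for H3K4me3, 65.8% for H3K4me2, 69.5% for H3K27ac and 65.1% for PolII. The median of all regions was 0.20 for H3K4me2, 0.69 for H3K27ac and 0.68 for PolII, so relative to it, regions open in both were at -0.28, -0.18 and -0.20 and regions open in Wt only at 1.43, 0.88 and 0.89. Under TMM the open-in-both medians of H3K27ac and PolII flipped to -0.17 and -0.18. Regions higher and lower in Wt by at least 2-fold numbered 951 and 583 for H3K4me3, 177 and 626 for H3K27me3, and 1149 and 280 for H3K4me2 (TMM 1052 and 417). For H3K27ac they numbered 1404 and 43 (TMM 738 and 311) and for PolII 1505 and 265 (TMM 959 and 691). The share above 0 was 82.0% for H3K27ac (50.2% under TMM) and 71.998% for PolII (51.1%).

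Pre-B-cell receptor signalling genes (16 genes) had median log2 ratios of 1.69 for H3K4me3, -0.20 for H3K27me3, 1.35 for H3K4me2, 1.98 for H3K27ac and 2.18 for PolII, at percentiles 99.99, 11.9, 99.6, 99.93 and 99.95 of matched lists. For H3K27ac 15 of them were at least 2-fold higher in Wt (TMM 9), and for PolII 12 (TMM 9). B-lineage factors (13 genes) were at 0.18, -0.55, -0.19, 1.20 and 1.295 for the same marks, at 97.3, 32.2, 67.0, 95.5 and 94.5. Cytokine receptors and surface proteins (7 genes) were at 0.67, -1.15, 1.15, 1.54 and 2.106, at 95.7, 8.90, 88.2, 97.1 and 97.0. Recombination genes (4 genes) were at 0.68, 0.56, 0.32, 0.36 and 2.21, at 86.0, 89.6, 35.4, 25.2 and 95.8. Cell cycle regulators (4 genes) were at -0.69, -0.21, -0.51, 0.31 and 0.43, at 33.2, 17.4, 20.5, 23.4 and 41.6. Cd5 alone stood for the T lineage, with PolII at 22.2 versus 3.42, and the myeloid gene Csf2ra had 17.6 versus 30.1.

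**Figure D4:**
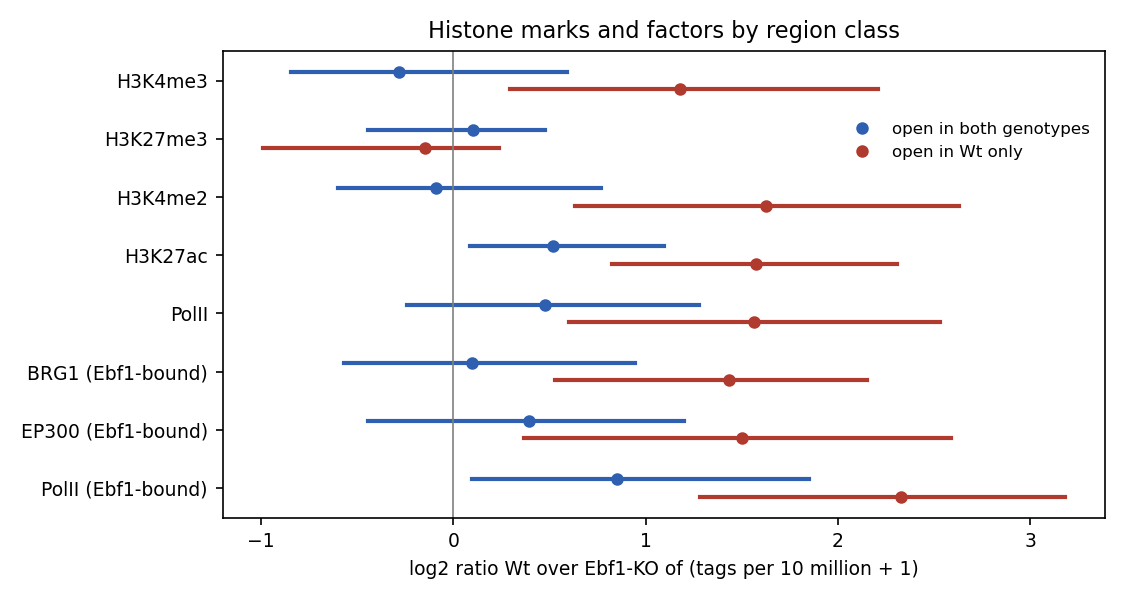
Median log2 ratio of Wt over Ebf1-KO tags per 10000000 plus 1 (x axis) for each mark or factor (y axis), with lines for quartiles over regions; blue dots are regions open in both genotypes, red dots regions open in Wt only. For H3K4me3 the medians were -0.28 and 1.18, for PolII at Ebf1-bound regions 0.85 and 2.33; under TMM the blue medians of H3K27ac, PolII, BRG1 and EP300 lay below 0.

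The comparison at Ebf1-bound regions asked whether the remodeller BRG1, the acetyltransferase EP300 and PolII occupy them without Ebf1. Igll1, Cd79a, the distal Foxo1 region and a Tcf3 intron had more of all 3 in Wt. So had Lef1, but at a different strongest region for each of the 3. Spib, Ccnd3 and Bcl2l1 had more BRG1 without Ebf1. The Wt EP300 library carries an antibody label that names PolII with a question mark, so its target is uncertain.

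BRG1 at Cd79a was 36.3 versus 7.55 (Wt first), at Igll1 18.5 versus 5.45, at the distal Foxo1 region 40.1 versus 6.92, at an intron of Lef1 (chr3:131117406-131118372) 43.1 versus 3.36 and at the Tcf3 intron 27.8 versus 5.66. At Pik3ap1 (42.8 versus 32.5) it differed less, and at Vpreb2 (28.6 versus 28.9) and Dok3 (49.2 versus 56.8) no difference was detectable at this depth. Spib had 14.4 (11.3–17.999) versus 43.6 (37.9–50.0), 3.03-fold (2.32–4.00) lower in Wt, and Ccnd3 (24.2 versus 46.8), Bcl2l1 (22.9 versus 39.2) and Cxcr4 (10.4 versus 37.5) were lower too. Ufm1 (chr3:53977358-53977917) held 42.6 (37.2–48.5) in Wt and was listed at 0 in Ebf1-KO, Grb7 was 19.9-fold (11.5–37.9) higher, and Grm4 (4.35 versus 44.9) and Fosb (8.33 versus 45.5) were lower in Wt.

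In the EP300 libraries, Igll1 had 82.0 (73.5–91.3) versus 3.45 (2.16–5.22), 23.8-fold (15.5–38.5) higher in Wt, Cd79a 45.8 versus 2.19 and Fcrla 85.7 versus 10.5. The distal Foxo1 region had 96.6 versus 8.93, Rag2 73.3 versus 7.83 and Lef1 (chr3:131106026-131107747) 60.4 versus 9.56. The Tcf3 intron had 70.8 versus 7.36, Dntt 36.0 versus 10.8 and Bst1 90.0 versus 50.6. Spib (20.4 versus 52.5) and Fosb (5.11 versus 45.1) were lower in Wt, and the Ccnd3 log2 ratio of 0.45 flipped to -0.14 under TMM. Alpl was 125-fold (56.9–342) higher in Wt, and Nedd9 71.9-fold (34.5–180.2) higher. PolII at the same set of regions had Igll1 and Lef1 as above, Vpreb1 at 58.9 versus 3.08, the complement regulator C4bp at 55.4 versus 0.34, Dntt at 48.4 versus 4.10 and Ccr7 at 35.9 versus 10.3, while Ebf1 (7.02 versus 3.08) had no difference detectable at this depth.

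Medians of the log2 ratio over 916 open and 256 closed regions were 0.10 and 1.43 for BRG1, 0.40 and 1.4998 for EP300, and 0.85 and 2.33 for PolII. The medians of all regions were 0.29, 0.56 and 1.10, so relative to them open regions were at -0.19, -0.16 and -0.25 and closed regions at 1.15, 0.94 and 1.23, and under TMM the open medians flipped to -0.19, -0.14 and -0.25. At least 2-fold higher in Wt were 64.5% of closed regions for BRG1, 62.5% for EP300 and 79.3% for PolII. Higher and lower counts over all regions were 380 and 117 for BRG1 (TMM 318 and 188), 433 and 129 for EP300 (TMM 311 and 254), and 621 and 41 for PolII (TMM 348 and 240). The shares above 0 were 61.4%, 66.9% and 81.9% (TMM 50.1%, 50.9% and 51.2%). B-lineage factors (9 genes) had medians of 2.113 for BRG1, 0.86 for EP300 and 1.55 for PolII, at percentiles 99.89, 67.8 and 84.5. Pre-B-cell receptor signalling genes (13 genes) were at 0.50, 1.37 and 2.68, at 93.85, 94.7 and 98.8, cytokine receptors (6 genes) at 0.41, 0.98 and 2.32, at 59.7, 72.7 and 96.3, and cell cycle regulators (3 genes) at -0.75, 0.14 and 0.15, at 10.6, 33.2 and 18.35.

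The peak comparison asked whether Ebf1-bound regions already open without Ebf1 more often hold Fli1 or Ikzf1, factors present in progenitors, in Wt cells. Open regions of Foxo1, Lef1, Spib, Blk, Bcl2l1 and Cdkn2c held peaks of both. Cd79b and Il2ra held both in closed regions. The Igll1 promoter had an Ikzf1 peak without Fli1, and Cd79a, Pou2af1, Dok3, Fcrla and Bst1 had Fli1 without Ikzf1. Vpreb1, Blnk and Ebf1 had neither. Of the 14 open regions of pre-B-cell receptor signalling genes, 12 had a Fli1 peak and 5 an Ikzf1 peak, and of the 14 open regions of B-lineage factors 11 and 7.

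Of 27261 Fli1 peaks and 5741 Ikzf1 peaks, some fell in 635 of 916 open regions for Fli1 (69.3%, 66.3–72.2) and in 135 of 256 closed regions (52.7%, 46.6–58.8), an odds ratio of 2.03 (Fisher's exact test over regions, p = 1.2e-06, Benjamini-Hochberg adjusted over 2 tests 2.4e-06). For Ikzf1 it was 276 open (30.1%, 27.2–33.2) and 48 closed regions (18.8%, 14.4–24.0), an odds ratio of 1.87 (Fisher's exact test, p = 2.7e-04, adjusted 2.7e-04). Both factors were at 27.3% of open and 14.8% of closed regions, and neither at 27.8% and 43.4%. Open regions were also more accessible in Wt, where the peaks were called. Their median was 45.0 tags over 746 matched regions, against 16.0 over 160 closed ones. Whether the difference in peaks remains at equal Wt accessibility was not tested. Without promoters the odds ratios were 1.83 for Fli1 and 1.92 for Ikzf1. Closed regions were shorter, with a median of 664.5 against 1090 bp. Within 500 to 1000 bp, the odds ratio was 1.31 for Fli1 (Fisher's exact test, p = 0.172) and 2.07 for Ikzf1 (p = 0.00268).

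**Figure D5:**
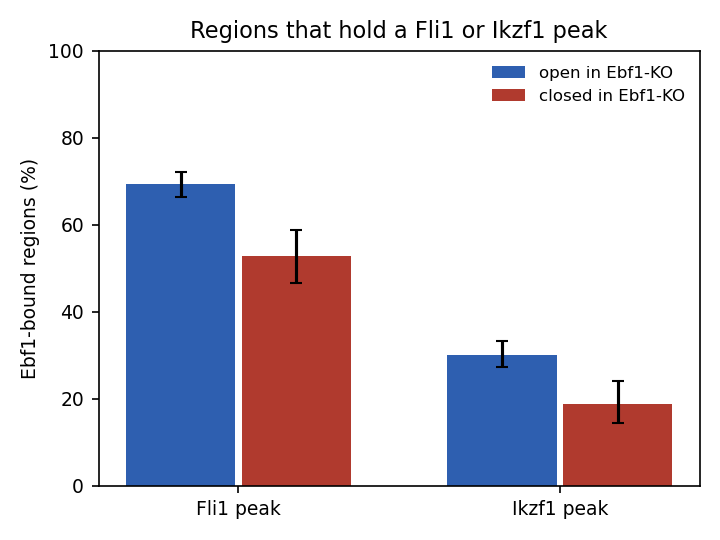
Percent of Ebf1-bound regions with a Wt peak (y axis) for Fli1 and Ikzf1 (x axis), bars for the 916 regions open and the 256 closed in Ebf1-KO, error bars Wilson 95% intervals. Shares were 69.3% and 52.7% for Fli1 and 30.1% and 18.8% for Ikzf1.

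The PLAC-seq data asked which accessible regions of the Abelson line take part in contacts of H3K4me3-marked promoters. Myc had 73 interactions, Bcl6 49, Runx1 42 and Foxo1 41, against a median of 6 over the promoters of 6129 genes. Mef2c (29), Bcl11a (28), Ebf1 (28), Lef1 (27), Nfil3 (23) and Cdk6 (22) followed. Of the Foxo1 promoter's partner bins, 5 held an Ebf1-bound region and 3 of these held one closed in Ebf1-KO. Lef1 had 4 with 1 closed, Myc 3 with 2 closed, and Ebf1 2 with 1 closed. Bcl6 had 1, and Runx1, Mef2c, Bcl11a, Nfil3 and Cdk6 had 0. The share over all promoters was not computed. Median spans were 805 kb for Myc, 635 kb for Bcl6, 440 kb for Foxo1, 360 kb for Ebf1 and 220 kb for Lef1.

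By list, median interactions per promoter were 16 for progenitor factors (6 genes), 14 for B-lineage factors (18 genes) and 11.5 for natural killer genes (4 genes). They were 10 for housekeeping (11 genes) and 9 for cell cycle genes (12 genes). T-lineage genes (6 genes) had 3.5, and pre-B-cell receptor (13 genes) and recombination genes (6 genes) had 3. Cytokine receptors (9 genes) had 2, myeloid genes (4 genes) 0.5 and the 1 erythroid gene 0. The natural killer genes were Nfil3, Id2, Il2rb and Klrd1, with 23, 21, 2 and 2 interactions, and Id2 is also in the progenitor list. The 69898 interactions had a median span of 130 kb (quartiles 55 and 260 kb) and a median of 16 contacts. They joined promoters with promoters in 6.60%, promoters with other accessible regions in 23.6%, promoters with no accessible region in 22.6%, and held no accessible promoter in 47.2%. Of 65093 accessible regions, 37065 (56.9%, 56.6–57.3) lay in an anchor. Promoters did so in 6739 of 7526 cases (89.5%, 88.8–90.2) and other regions in 30326 of 57567 (52.7%, 52.3–53.1), an odds ratio of 7.69, a direction that the H3K4me3 enrichment of the assay sets. Of Ebf1-bound regions, 216 of 256 closed (84.4%, 79.4–88.3) and 850 of 916 open (92.8%, 90.9–94.3) lay in an anchor.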

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

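No paired analysis was possible because each group is 1 column, pooled or from a single library, so replicate numbers cannot be matched. For the same reason the planned edgeR quasi-likelihood and DESeq2 tests, leaving out each replicate and the replicate block were not run. Subtraction of input or IgG was not run because the region tables hold no such columns, and a selection of the accessible regions of the Abelson line by higher score was not run because every score is 0. TMM for the class medians of the marks and factors, the summed values and the 500 to 1000 bp window were chosen after the data were seen. Of all values compared with an alternative, 204 stayed the same, 374 moved, 18 reversed and 1 was weaker. None of the regions named for their largest ratios reversed, with 93 moved and 92 the same under TMM and 138 moved and 47 the same with a pseudocount of 5. A pseudocount cannot change the sign of a ratio, and these regions were picked for large ratios. The absence of reversals among them is therefore no evidence of robustness. Class medians moved in 17, reversed in 17 and stayed in 10 cases under TMM, moved in 35 and stayed in 9 with the pseudocount of 5, and moved in 29, reversed in 1 and stayed in 11 with a mean of at least 10.

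TMM takes the bulk of regions as unchanged, so it removes any shift they share. Some other regions of listed genes did reverse under it, such as the Foxo1 exon (0.28), the Ebf1 promoter (0.08) and the Tcf3 promoter (0.53) in E2A-KO. Under TMM the regions with a 2-fold difference in E2A-KO numbered 1044 (294 higher and 750 lower). At 6 h 40 were higher, at 24 h 101 differed (70 higher) and at 72 h 112 differed (80 higher). Medians that reversed in E2A-KO were those of all regions (0.0169), regions in neither class (0.35) and regions open in both away from promoters (0.00930) and at promoters (0.0241). In the time course they were those of all and of open regions at 6 h (-0.00758 and -0.00949), 24 h (-0.0475 and -0.0527) and 72 h (-0.0563 and -0.0626). For regions open in both, they were H3K27ac away from promoters (-0.16) and at promoters (-0.22), and PolII likewise (-0.16 and -0.27). For open Ebf1-bound regions they were BRG1 (-0.19), EP300 (-0.14) and PolII (-0.25).

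A pseudocount of 5 shrinks ratios of low values by construction. With it, 1290 regions differed in E2A-KO (15 higher), 17 at 6 h (17 higher), 91 at 24 h (91 higher) and 119 at 72 h (119 higher). For H3K4me3 and H3K27me3 together 1222 differed, with 598 higher in Wt and 347 higher in Ebf1-KO for H3K4me3, and 2 and 275 for H3K27me3. The difference between class medians, closed or Wt-only minus open, became 0.79 for H3K4me3, -0.0696 for H3K27me3, 1.07 for H3K4me2, 0.54 for H3K27ac, 0.46 for PolII, 0.83 for BRG1, 0.57 for EP300 and 0.88 for PolII at Ebf1-bound regions, from 1.46, -0.25, 1.72, 1.06, 1.09, 1.34, 1.10 and 1.47.

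A mean of at least 10 tags leaves fewer regions. In E2A-KO 1276 of 2391 then differed (17 higher and 1259 lower), at 6 h 24 (24 higher), at 24 h 107 (107 higher) and at 72 h 137 (137 higher). For H3K4me3 and H3K27me3 together 950 differed, with 442 higher in Wt and 375 higher in Ebf1-KO for H3K4me3, and 0 and 133 for H3K27me3. The differences of class medians were 2.43 for H3K4me3, -0.65 for H3K27me3, 2.36 for H3K4me2, 1.69 for H3K27ac, 2.25 for PolII, 1.64 for BRG1, 2.30 for EP300 and 2.12 for PolII at Ebf1-bound regions. H3K27me3 at regions open in both away from promoters reversed to -1.63, over 100 regions.

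The closed minus open level against 0 h turned from slightly negative to 0.0553 at 6 h, 0.16 at 24 h and 0.23 at 72 h with summed values, in which the strongest regions weigh most, and was -0.19 at 24 h with medians over regions. The cause was not tested. The Fli1 odds ratio was weaker within 500 to 1000 bp, at 1.31. The share of accessible regions in a PLAC-seq anchor was 54.8% with 50% overlap and 48.2% with q under 0.01. Interactions numbered 43650 with q under 0.01 and 33924 with both anchors on accessible regions. The median span was 120 kb with q under 0.01, 110 kb with at least 10 contacts and 120 kb with both anchors accessible.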

Other observations

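Coordinate-matched regions allowed the induced cells to be set beside Wt. The 746 matched open regions had median levels of 45.0 tags in Wt, 14.6 in E2A-KO, 13.5 at 0 h and 22.6 at 72 h of 4OHT, and the median region stood at 39.5% of its Wt level at 0 h and 60.7% at 72 h. The 160 matched closed regions had 16.0 in Wt, 3.91 in E2A-KO, 3.17 at 0 h and 4.61 at 72 h, with 20.0% and 28.2% for the median region. Closed regions at 50% of the Wt level or more numbered 13 at 0 h and 33 at 72 h (TMM 17), and open regions 277 and 463 (TMM 264). These gains rest on library totals. With the TMM shift of -0.59 for 72 h over 0 h, the median open region stood at 40.3% at 72 h. The median closed region then stood at 18.7%. This shift does not scale the 4OHT columns to the Wt column. Only the Wt column's name gives a fragment size setting, and only the 4OHT columns' names mention removal of mitochondrial reads. How far these differences set the percentages and counts relative to Wt was not tested.

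At closed Ebf1-bound regions, EP300 and PolII values were correlated in Wt (Spearman's rho 0.75) and less so in Ebf1-KO (0.35), and EP300 and BRG1 likewise (0.71 and 0.53). Counting error weighs more at the lower Ebf1-KO values of closed regions, and its share in this drop was not tested. The antibody label of the Wt EP300 library names PolII, so its correlation with PolII leaves the target open. At open regions the correlations held without Ebf1, at 0.72 and 0.74 for EP300 with PolII and 0.73 and 0.85 for EP300 with BRG1. Away from the closed class, Ebf1-bound regions had higher Wt over Ebf1-KO ratios of H3K27ac than other open regions, at median log2 ratios of 0.84 and 0.41. Those of H3K4me2 were 0.19 and -0.16, all with library totals.

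The tests for a growing signal-to-background difference of PolII, for the share of tags in accessible regions and for region length within levels in E2A-KO, and for closing of Y-linked regions were chosen only after their results were seen. PolII was higher in Wt at Ebf1-bound regions that are open in both genotypes with library totals, but TMM scaling over Ebf1-bound regions alone reversed the median of the 916 open ones, from 0.85 to -0.25. What does not depend on this scaling is their difference from other open regions, 0.50 (0.40–0.61), which a single scaling factor for the whole library would not have left. Within 10 bins of equal size by PolII level the median difference was 0.504, positive in 9 of 10. It was -0.17 in the lowest bin and 1.09 in the highest. The bins were set on the mean of both genotypes, which holds the compared values. A signal-to-background difference that grows with the level therefore stays open. The larger Wt over Ebf1-KO ratio of PolII at Ebf1-bound than at other open regions may still depend on Ebf1. Replicated PolII ChIP with spike-in after induction of Ebf1 could test this hypothesis, while a higher PolII level as such stays open. A contribution of the genes for which the regions were selected was not tested.

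ATAC signal was higher at 72 h than at 0 h in both region classes. Counting noise alone would not give this, since 23.8% of closed regions were at least 2-fold higher, against 1.05% in simulated unchanged regions. The simulation held no shift common to all regions, so counting noise on top of such a shift was not excluded. A signal-to-background difference between the pooled libraries remains possible, because promoters and other open regions differed by only -0.0381 (-0.11 to 0.01). All these regions are Ebf1-bound in the Abelson line, so an effect of Ebf1 on every region could give the same. Closed regions with a Pax5 peak did not gain more, at a difference of -0.18 (-0.37 to 0.12), and open regions with a Fli1 peak did not keep more BRG1 without Ebf1, at 0.0893 (-0.08 to 0.32).

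ATAC signal was lower in E2A-KO over most regions. The fragment size setting of the Wt column would make narrow regions lose more, and rho between region length and ratio was -0.16 (-0.20 to -0.13), but long regions also hold more tags, and within 5 bins of the Wt level rho had a median of 0.27, so this explanation stays open. A library-wide difference in the share of tags in accessible regions would give the same ratio at the same level and length. In 15 bins of both, regions open in Wt only were lower than regions open in both in all 15. The median difference was -1.16, and it was -0.54 in the bin where they differed least. A library-wide difference alone would not give this excess of that class. The bins were set on the Wt value, which is part of the ratio, and the effect of this choice was not tested. The shift common to all regions stays open, since TMM scaling removes any such shift whatever its cause.

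The Ebf1-KO ChIP libraries held 0 tags of H3K4me2 and PolII at 4 Y-linked regions, while CUT&RUN of H3K27ac in Ebf1-KO did reach them. Summed H3K4me3 was 0.10 in Ebf1-KO and 162 in Wt. H3K27me3 was near the floor in both, at 0.45 (0.11–1.23) and 1.29 (0.59–2.45), so it cannot tell. BRG1 and EP300 had no Y-linked regions to compare. Closing of these regions without Ebf1 was excluded as the explanation, since 0% (upper bound 1.13%) of 337 other regions open in Wt only, at Wt values no lower, held 0 tags of both. All 4 regions are classed as open in Wt only, so they were not called accessible in Ebf1-KO either. The Ebf1-KO cells used for ChIP of H3K4me2 and PolII may thus lack a Y chromosome and differ in source from those used for CUT&RUN. Cells from littermates of known sex could settle this.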
